A study of Danio rerio with 8 samples.

How the data were processed

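PolyA RNA from whole 5-day-old zebrafish larvae was sequenced from stranded libraries, 4 from wild types and 4 from upf1 mutants, per the labels. The authors deposited a table of gene counts on GRCz10, and per the submitters' processing notes featureCounts was among the tools. The notes also name bcl2fastq 2.17.1.14, STAR 2.5.2b, SAMtools 1.3.1, Salmon 0.7.2, TopHat2 2.0.13 and R 3.3.1, without saying which step each served, so the aligner behind the counts is not given in the sources used here. The deposited transcript table holds p-values and q-values from the authors' run of sleuth, of which the submitters' processing notes name version 0.28.1, and no effect sizes or gene names. The deposited splicing tables hold p-values, FDR values, junction counts and inclusion levels for 5 event classes, in the columns that rMATS writes, per the file headers. The rMATS version and settings, the strand setting of the counting and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

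Gene symbols came from the splicing tables for 12446 of 31953 genes and from a table of gene names for 14122, and 5385 had none. Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test, TMM scaling and filterByExpr (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were computed from the deposited counts with the same scaling. Gene lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of 862 list entries, 80 had no match and 23 were ambiguous. There were 27 lists, 25 of them written from textbook knowledge and the others from a rule on symbols, all before the data were examined. Overlaps were tested with Fisher's exact test and within quartiles of expression. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the deposited splicing and transcript tables, taken at an FDR or q of 0.05.

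The rule for named genes was set before the data were examined. It took upf1, rpl10a, the 12 largest rises and 12 largest falls that passed, with a mean log2 CPM of at least 1 and groups that did not overlap, and up to 4 members per list by adjusted p. For splicing it took the rpl10a events, the 2 largest differences among the 20 smallest FDR values per class, and up to 3 events for each of the NMD, splicing regulator and ribosomal protein lists. Some further genes were chosen after their values were seen, and the text says so.

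The test was checked on simulated counts for the comparison of mutants with wild types over 23425 genes. It recovered 22.4% of genes changed 1.5-fold, 64.2% at 2-fold and 97% at 4-fold, with 6 false calls among 128. A planted list of 30 genes changed 1.5-fold was called, and 0 of 40 random lists were. The simulated genes varied independently, unlike some real lists, such as ribosomal proteins (estimated inter-gene correlation 0.875). The check thus does not show how often camera would falsely call lists whose members vary together.

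Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a CPM of at least 1 in 4 libraries, DESeq2 1.42.0, limma voom, a replicate block, leaving out each library, and stricter thresholds for the deposited tables. A planned split of transcripts by biotype was not run because no annotation matched them, and no transcript is named. The results of 1 gene list and some single genes, tested with the rest, are not reported here.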

Results

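Whole zebrafish larvae of the TLEK strain were profiled by polyA RNA sequencing 5 days after fertilization, with 4 libraries from wild types and 4 from fish homozygous for a nonsense mutation in upf1. The gene upf1 encodes the central RNA helicase of nonsense-mediated decay (NMD), the pathway that degrades transcripts with a premature stop codon. Per the labels, the experiment asked what upf1 does in lymphocyte development. Gene counts summed to 88911873, 75335048, 90453382 and 94331733 in mutant replicates 1 to 4. They summed to 87715388, 96104507, 87994091 and 86872276 in wild type replicates 1 to 4. Levels are given as CPM (counts scaled to library size), mean ± SD over n = 4 libraries per genotype. The labels do not say whether the replicates came from separate clutches or how many larvae made up a library, so p-values measure the spread between these libraries. Because RNA came from whole larvae, a changed level cannot be told from a changed share of the cells that express the gene.

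The upf1 mRNA itself (ENSDARG00000016302) was 2.21-fold higher in mutants, at 285 ± 7.51 CPM against 129 ± 4.35 (log2 fold change 1.146, SE 0.0699, adjusted p = 8.34e-06). It lay at 288, 276, 294 and 284 CPM in mutant replicates 1 to 4 and at 132.5, 122.6, 130.1 and 130.5 CPM in wild type replicates 1 to 4. A nonsense mutation need not lower the mRNA, so this level does not check the genotype labels. Of 23680 genes tested with edgeR's quasi-likelihood test, 2159 were higher and 1223 lower in mutants after Benjamini-Hochberg adjustment (14.3% of those tested). Of these, 670 rose and 241 fell by more than 2-fold. The 4 mutants lay on one side of the 4 wild types for 5010 genes (21.2% of those tested, against 2.86% by chance). The number of genes lower was less stable than the number higher: it was 678 without mutant replicate 1, and 812, 683 and 675 without wild type replicates 1, 3 and 4. The number higher was 1435 without wild type replicate 3, and the DESeq2 Wald test called 2107 genes lower.

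Among the largest rises with all mutants above all wild types was nupr1b, a stress-induced nuclear protein, at 1296 ± 319 against 57.9 ± 16.4 CPM (22.4-fold, adjusted p = 8.34e-06). The noncoding host gene of small nucleolar RNAs gas5 rose 10.1-fold (125 ± 14.5 against 12.35 ± 1.49 CPM, adjusted p = 4.21e-07). The others were bmb (12.9-fold), GADD45G (ENSDARG00000019417, 10.6-fold), rbp7a (9.64-fold), C8H9orf3 (8.89-fold), EGFL7 (8.32-fold), the myosin heavy chain gene myh7ba (8.10-fold), ftr12 (8.03-fold), jac8 (31.8-fold) and jac9 (84.3-fold, from 0.0651 ± 0.0234 to 5.59 ± 3.64 CPM). The glucokinase gene gck averaged 34.45 ± 37.2 against 1.02 ± 0.422 CPM (33.8-fold, adjusted p = 0.0357). Its call was lost without any 1 of mutant replicates 1 and 3 or the 4 wild types, with adjusted p between 0.0656 and 0.106 and a log2 fold change of 4.33 without mutant replicate 3. The jac8, jac9, ftr12 and GADD45G levels are uncertain because these genes have close relatives that may share reads.

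Among the largest falls were the hemopexin gene hpxa, whose protein binds haem in plasma (log2 fold change -6.23, SE 0.764, 0.310 ± 0.213 against 23.0 ± 14.97 CPM, adjusted p = 0.00175) and the cytochrome P450 gene cyp2ad2 (6.66-fold lower, 8.004 ± 1.143 against 53.3 ± 4.96 CPM, adjusted p = 1.29e-06). RAG1, which encodes a recombinase subunit for antigen receptor genes, fell too (-2.61, 1.93 ± 0.632 against 11.8 ± 2.43 CPM, adjusted p = 1.56e-04). The genes IGFALS (-2.73), C20H6orf58 (ENSDARG00000095751, -2.12), shbg (-2.07), tgm2a (-2.01) and the complement regulator gene rca2.2 (-1.99) fell with adjusted p at or below 0.00417. Both genes of class II antigen presentation in this group, mhc2dab (-2.07, adjusted p = 0.0328) and cd74b (-2.06, adjusted p = 0.0257), lost their calls when libraries were left out. This held for mhc2dab without mutant replicates 1 or 3 or wild type replicates 1, 2 or 4 (adjusted p 0.0655 to 0.0834), and cd74b without mutant replicates 1 or 3 or any 1 wild type (0.0503 to 0.0744). The lipase gene CEL (ENSDARG00000017490, -2.92, adjusted p = 0.0475) was called only with all libraries or without mutant replicate 2, and reached 0.0731 to 0.107 without any other. The gene MYH11 (-2.167, adjusted p = 0.0315) was lost without mutant replicates 2, 3 or 4 or wild type replicates 1, 3 or 4 (0.0531 to 0.0803), and its log2 fold change was -1.54 without wild type replicate 4. Levels of mhc2dab and CEL are uncertain because of near-identical relatives.

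**Figure D1:**
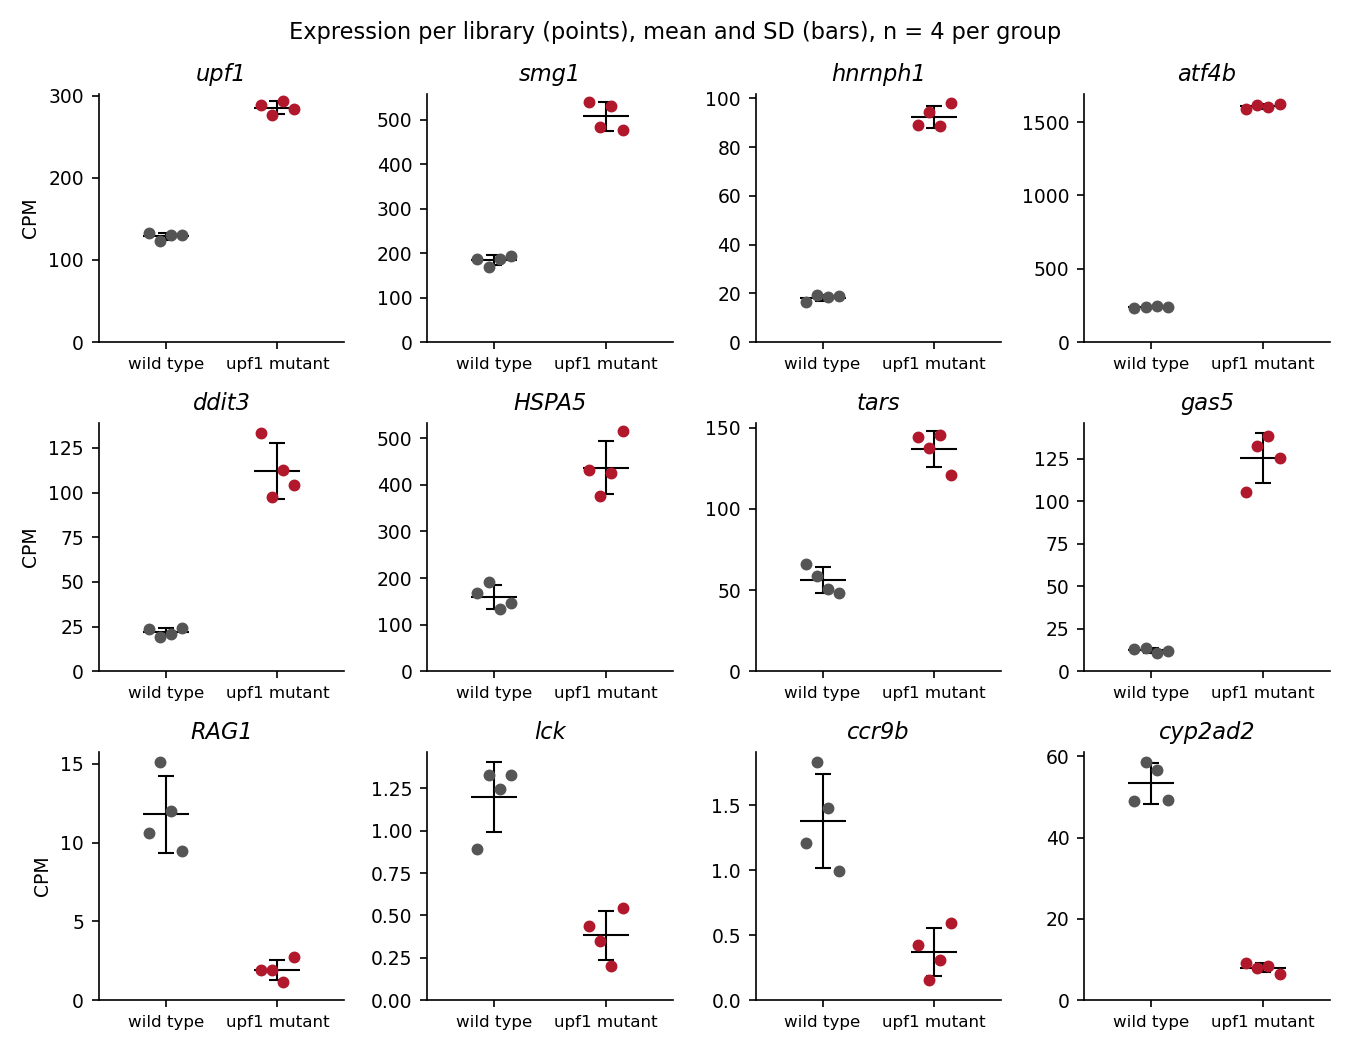
CPM of 12 named genes in each library (points; grey, wild type; red, upf1 mutant), with the mean (line) and SD (bars) of n = 4 libraries per genotype. In each panel all 4 mutants lie on one side of all 4 wild types, above them for upf1, smg1, hnrnph1, atf4b, ddit3, HSPA5, tars and gas5 and below them for RAG1, lck, ccr9b and cyp2ad2.

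Some genes of the decay machinery and most listed splicing regulators were higher in mutants. Of 21 measured NMD and exon junction factors, 9 rose (the mutated gene upf1 itself among them), 0 fell and 12 did not pass. When adjusted over the list alone, 1 fell and 10 rose. They included the kinase gene smg1 (2.76-fold, 508 ± 32.3 against 184 ± 11.3 CPM, adjusted p = 7.57e-06), the endonuclease gene SMG6 (2.01-fold, adjusted p = 5.79e-05) and smg5 (1.63-fold, adjusted p = 8.24e-05). Against 0 lower in edgeR, 1 member was lower at an unadjusted p under 0.05, DESeq2 called 1 lower and limma voom 0. Of 41 SR and related splicing regulators, RNA-binding proteins that steer splice site choice, 31 rose, 0 fell and 10 did not pass (35 rose and 1 fell when adjusted over the list alone). In edgeR 1 was lower at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 lower. Examples were hnrnph1 (5.06-fold, 92.5 ± 4.45 against 18.3 ± 1.23 CPM, adjusted p = 3.42e-07), ptbp1b (3.1-fold), tra2b (2.46-fold) and srsf10a (2.34-fold). Camera placed both lists above other genes (adjusted p = 5.30e-08 for the NMD list and 1.39e-49 for the splicing list), and both calls held with an estimated correlation (adjusted p = 0.00733 and 0.00453). Without wild type replicate 2, 1 splicing regulator was called lower.

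Many genes of the amino acid and endoplasmic reticulum stress programs were also higher. In the ATF4 and amino acid stress list 19 of 34 members rose, 0 fell and 15 did not pass (22 rose and 0 fell when adjusted over the list alone). After nupr1b, the largest rises in this list were those of the transcription factor genes atf4b (6.69-fold, 1609 ± 16.1 against 241 ± 6.38 CPM, adjusted p = 2.85e-07), atf5b (5.55-fold, adjusted p = 4.21e-07) and ddit3 (5.11-fold, adjusted p = 3.10e-06). The list was above other genes by camera (adjusted p = 6.26e-28, and adjusted p = 0.00291 with an estimated correlation). In the unfolded protein response list, 17 of 23 members rose, 0 fell and 6 did not pass (18 rose and 1 fell when adjusted over the list alone). Among them were the chaperone gene HSPA5 (2.74-fold, 437 ± 57.7 against 160 ± 25.4 CPM, adjusted p = 1.41e-04), calr3b (1.93-fold), CALR (1.65-fold) and the transcription factor gene xbp1 (1.62-fold). Of 16 aminoacyl-tRNA synthetase genes, some of them also named in the ATF4 list, 13 rose, 0 fell and 3 did not pass (14 rose and 0 fell when adjusted over the list alone). Examples were tars (2.45-fold, 137 ± 11.1 against 56.0 ± 8.08 CPM, adjusted p = 8.17e-05), aars (1.92-fold), cars (1.79-fold) and yars (1.74-fold). Camera called both lists higher (adjusted p = 3.61e-15 and 1.43e-13), but not with an estimated correlation (adjusted p = 0.0807 and 0.159). For the 0 lower in these lists, edgeR had 1, 1 and 0 members lower at an unadjusted p under 0.05 in the ATF4, unfolded protein and synthetase lists. DESeq2 called 0, 1 and 0 lower there, and limma voom 0 in each.

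The apoptosis list was not called by camera (adjusted p = 0.262), but fry called it higher (adjusted p = 0.0337). Of its 26 members, 4 were higher, 1 lower and 21 did not pass (5 higher and 3 lower when adjusted over the list alone). The caspase inhibitor gene birc2 (1.85-fold), apaf1 (1.75-fold), casp8 (1.94-fold) and, named after its values were seen, mcl1a (1.42-fold) rose, and xiap fell (log2 fold change -0.66). The calls of mcl1a and xiap were lost without wild type replicate 3 (adjusted p = 0.0560) and wild type replicate 4 (adjusted p = 0.0524). Members lower numbered 2 without mutant replicate 1, mutant replicate 3 or wild type replicate 2.

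Of 28 measured T cell and thymocyte genes, 9 fell, 1 rose and 18 did not pass (12 fell and 1 rose when adjusted over the list alone). After RAG1 came the T cell kinase gene lck (log2 fold change -1.65, 0.382 ± 0.144 against 1.199 ± 0.209 CPM, adjusted p = 0.00871). The thymus-homing receptor gene ccr9b (-1.89, 0.371 ± 0.185 against 1.38 ± 0.359 CPM, adjusted p = 0.0114) and the thymocyte selection gene THEMIS (-1.21, adjusted p = 0.0177) fell too. Named after their values were seen, RUNX3 (-0.57), il7r (-1.11), ZAP70 (-1.80), RAG2 (-0.68) and cd4 (-1.64) fell, and cd4-2.2, which encodes a CD4-related protein, rose (1.59, adjusted p = 0.0423). Camera called the list lower (adjusted p = 4.46e-05), and the call was lost with an estimated correlation (adjusted p = 0.159). Many members had low counts: with a CPM of 1 required in 4 libraries, lck, ccr9b, THEMIS, il7r, ZAP70, cd4 and cd4-2.2 were not tested, 3 members were lower and the median log2 fold change went from -0.459 to -0.142. The count of members lower was 3 without wild type replicate 1 and 5 without wild type replicate 3, and the cd4-2.2 call was lost without any 1 mutant or wild type replicates 1 or 3 (adjusted p 0.0565 to 0.111). THEMIS and RUNX3 were lost without wild type replicate 1 (adjusted p = 0.0513 and 0.0510), ZAP70 without mutant replicate 1 or wild type replicates 1, 3 or 4 (0.0534 to 0.0575), and il7r without those or mutant replicate 3 (0.0554 to 0.0627). RAG2 was lost without mutant replicates 1, 2 or 3 or wild type replicates 1, 2 or 3 (0.0552 to 0.0778), and cd4 without mutant replicates 2 or 3 or any 1 wild type (0.06 to 0.0822).

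The haematopoietic stem and progenitor list was not called (adjusted p = 0.857), with MYCN (1.43-fold, adjusted p = 0.00238) and gfi1aa (1.89-fold, adjusted p = 0.00834) the 2 of 17 members that rose (2 rose and 0 fell when adjusted over the list alone). In edgeR 0 fell, against 1 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 lower. Of 21 neutrophil genes, illr4 rose (11.6-fold, 0.873 ± 0.245 against 0.0739 ± 0.0612 CPM, adjusted p = 0.00343), as did the protease gene adam8a (1.62-fold, adjusted p = 0.0426), and 0 fell (1 rose and 0 fell when adjusted over the list alone). The list was not called (adjusted p = 0.675), 1 member was lower at an unadjusted p under 0.05 in edgeR, and DESeq2 and limma voom called 0 lower. The adam8a call was lost without mutant replicates 2, 3 or 4 or wild type replicates 1, 2 or 4 (0.056 to 0.114). There was 1 member higher without mutant replicate 4 or wild type replicates 2 or 4, and 1 lower without mutant replicates 2 or 4. Of 8 B and natural killer lymphocyte genes, cd79a, a B cell receptor chain gene, rose (6.36-fold, 0.680 ± 0.479 against 0.105 ± 0.0829 CPM, adjusted p = 0.0378), a call lost without mutant replicates 1 or 2 or wild type replicates 1, 2 or 4 (0.0743 to 0.0984). That list was not called (adjusted p = 0.918), with 1 higher and 1 lower when adjusted over the list alone. In edgeR 0 fell, against 1 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma voom and 1 without wild type replicate 2.

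The macrophage list was called lower (median log2 fold change -0.35, adjusted p = 0.0244, and adjusted p = 0.715 with an estimated correlation), with csf1rb (-1.12, adjusted p = 0.0134) and cd74b (-2.06) the 2 of 24 members that fell (2 fell and 0 rose when adjusted over the list alone). In edgeR 0 rose, against 1 at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom. Its median in mutant replicate 2 lay -1.87 on the log2 scale from the other 3 mutants, and the call was lost without that library (adjusted p = 0.141) and without wild type replicate 2 (adjusted p = 0.0976). Without mutant replicate 2, 4 members were lower and 2 higher, and without wild type replicate 2, 1 was higher. Members lower numbered 1 without mutant replicates 1 or 3 or wild type replicates 1, 2 or 4. Of 23 erythrocyte genes, 3 fell, 0 rose and 20 did not pass (6 fell and 0 rose when adjusted over the list alone). They were the embryonic globin gene hbbe1.2 (-0.91, adjusted p = 0.0151), nt5c2l1 (-0.71, adjusted p = 0.0110) and tmod4 (-0.77, adjusted p = 0.0113), an actin filament capping gene also active in skeletal muscle. In edgeR 1 erythrocyte member was higher at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 higher. The erythrocyte list was called lower (adjusted p = 0.00673, and adjusted p = 0.509 with an estimated correlation), with 5 members lower without mutant replicate 4. Erythrocyte genes in mutant replicate 2 had a median -0.327 on the log2 scale from the other mutants. Without that library the list's median log2 fold change was -0.266, against -0.369 with all libraries. In the thymic epithelium and thymus anlage list, which was not called (adjusted p = 0.898), hoxa3a (1.31-fold) and ascl1a (1.53-fold) rose, and the chemokine gene cxcl12a (-0.32) and the keratin gene krt8 (-0.45) fell, out of 16 members (2 rose and 2 fell when adjusted over the list alone). The krt8 call was lost without any 1 library except mutant replicate 4 (0.0505 to 0.0992), so that 1 member was then lower.

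Interferon and inflammation genes as a list were not called (adjusted p = 0.248), and 4 of 38 rose, 1 fell and 33 did not pass (4 rose and 1 fell when adjusted over the list alone). Those higher were irg1l (15.3 ± 1.28 against 7.05 ± 1.89 CPM, adjusted p = 0.00274), isg15 (3.56-fold, adjusted p = 0.00576), ifit14 (3.87-fold, adjusted p = 0.0197) and, named after its values were seen, irf9 (1.47-fold, adjusted p = 0.0273). The signal transducer gene stat2 fell (log2 fold change -0.34, adjusted p = 0.0267). The stat2 call was kept without mutant replicate 1 or wild type replicate 2 and lost without any other 1 library (0.0510 to 0.0703). The ifit14 call was lost without mutant replicate 1 or wild type replicate 1 (0.0534 to 0.0558), and the irf9 call without mutant replicates 1 or 4 or wild type replicates 1 or 3 (0.0508 to 0.0719). Without mutant replicate 1, 2 members were higher.

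Of 34 liver genes, 12 were lower in mutants, 2 higher and 20 did not pass (16 lower and 2 higher when adjusted over the list alone). The fetuin gene ahsg2 had the largest fall of the list (log2 fold change -3.52, SE 0.396, adjusted p = 4.25e-04). Besides cyp2ad2, the thyroid hormone carrier gene ttr (-1.77, 11.1 ± 2.14 against 37.8 ± 10.3 CPM, adjusted p = 5.92e-04) and the drug-metabolizing gene cyp3a65 (-1.21, adjusted p = 4.37e-04) fell. Named after their values were seen, the hepatic lipase gene lipca (5.00-fold, adjusted p = 6.06e-04) and the fibrinogen gene fgb (2.04-fold, adjusted p = 0.0295) rose. The list was called lower (adjusted p = 4.80e-09), but not with an estimated correlation (adjusted p = 0.229). The fgb call was lost without mutant replicates 2 or 4 or any 1 wild type (0.0551 to 0.0766), and 1 member was higher without mutant replicates 2 or 4 or wild type replicates 2, 3 or 4. Of 29 intestine genes, 3 fell, 0 rose and 26 did not pass (3 fell and 0 rose when adjusted over the list alone). They were the retinol-binding gene rbp2a (-1.08, 65.9 ± 11.3 against 139 ± 18.6 CPM, adjusted p = 8.86e-04), the peptide transporter gene slc15a1b (-0.94, adjusted p = 0.00214) and the alkaline phosphatase gene alpi.2 (-1.07, adjusted p = 0.00273). In edgeR 0 intestine genes were higher at an unadjusted p under 0.05, DESeq2 and limma voom called 0 higher, and 1 was called higher without wild type replicate 2. The intestine list was called lower (adjusted p = 0.0288, and adjusted p = 0.509 with an estimated correlation), a call lost without mutant replicates 2 or 3 (adjusted p = 0.0571 and 0.108) or wild type replicate 2 (adjusted p = 0.140).

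The exocrine pancreas list had the lowest median of the 27 lists (log2 fold change -1.5), yet edgeR called 0 of its 22 members (0 also when adjusted over the list alone). Unadjusted, 9 were lower and 1 higher at p under 0.05, the DESeq2 Wald test called 4 lower and limma voom called 1 lower. Mean log2 CPM over the list was 2.56 in mutant replicate 2, against 6.68, 6.82 and 6.72 in mutant replicates 1, 3 and 4 and 7.23 to 7.94 in wild types. Without that library, 13 members were lower, among them the elastase gene ela2l (-1.97, adjusted p = 8.58e-04), the chymotrypsinogen gene ctrb.2 (-1.76, adjusted p = 0.00118) and the carboxypeptidase gene cpa4 (-1.80, adjusted p = 0.00215), and without mutant replicate 1 there was 1. With all libraries ela2l stood at 270.0 ± 186 against 1397 ± 266 CPM (adjusted p = 0.101). Camera called the list lower (adjusted p = 2.27e-04), but not with an estimated correlation (adjusted p = 0.575). Reads of the digestive protease genes may be split among close relatives, so single members are uncertain.

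Of 37 fast skeletal muscle genes, 11 were lower, 0 higher and 26 did not pass (20 lower and 0 higher when adjusted over the list alone). Also 0 were higher at an unadjusted p under 0.05 in edgeR, and DESeq2 and limma voom called 0 higher. Examples were the myosin light chain genes mylz3 (log2 fold change -0.76, 3373 ± 281 against 5707 ± 768 CPM, adjusted p = 0.00395) and mylpfb (-0.75), the actinin gene actn3a (-0.77) and the myosin heavy chain gene myhz1.2 (-0.75). The list was called lower (adjusted p = 2.54e-07, and adjusted p = 0.491 with an estimated correlation), and 6 members were lower without mutant replicate 1, wild type replicate 1 or wild type replicate 3, and 7 without mutant replicate 2. The muscle median in mutant replicate 2 lay -0.372 on the log2 scale from the other mutants (quartiles -0.671 to -0.259). Of 31 photoreceptor genes, 10 fell, 0 rose and 21 did not pass (14 fell and 0 rose when adjusted over the list alone). In edgeR 0 were higher at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 higher. Those lower included the cone channel gene cnga3a (-0.81, 22.9 ± 3.42 against 40.2 ± 4.52 CPM, adjusted p = 0.00221), the cone transducin gene gnat2 (-0.64, adjusted p = 0.0130) and grk1b (-0.56, adjusted p = 0.0172). That list was called lower (adjusted p = 5.06e-05, and adjusted p = 0.509 with an estimated correlation), with 3, 4 and 6 members lower without mutant replicates 1, 3 and 4, and 6 without wild type replicate 3 or 4. In mutant replicate 2 the photoreceptor and lens lists had medians 0.46 and 0.47 above the other 3 mutants on the log2 scale. Of 50 lens crystallin genes, 2 rose, crygm5 (1.95-fold, adjusted p = 0.00799) and lim2.2 (1.95-fold, adjusted p = 0.0427), and the list was not called (adjusted p = 0.262). When adjusted over the list alone, 1 rose and 0 fell. In edgeR 0 fell, against 4 at an unadjusted p under 0.05, 4 in DESeq2 and 1 in limma voom. It was called lower without mutant replicate 2 (adjusted p = 0.0111, 4 members lower) and without wild type replicate 3 (adjusted p = 0.0320, 1 member lower), and the lim2.2 call was lost without any 1 library (0.0517 to 0.0935), which left 1 member higher.

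Neuron and cartilage lists were called lower with small medians. In the neuron list 6 of 39 members fell, 1 rose and 32 did not pass (6 fell and 1 rose when adjusted over the list alone). They included the neurofilament genes nefmb (log2 fold change -0.38, 33.0 ± 2.37 against 42.8 ± 2.59 CPM, adjusted p = 0.0135) and NEFL (-0.40, adjusted p = 0.0162), while the GABA synthesis gene gad1a was higher (1.49-fold, adjusted p = 0.0166). The neuron call (adjusted p = 0.0265, and adjusted p = 0.715 with an estimated correlation) was lost without mutant replicate 3 (adjusted p = 0.137), mutant replicate 4 (0.0629) or wild type replicate 4 (0.0941), and 2 members were lower without mutant replicates 1 or 3 or wild type replicates 3 or 4. In the cartilage and bone list 3 of 33 members fell, 0 rose and 30 did not pass (3 fell and 0 rose when adjusted over the list alone). In edgeR 2 were higher at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 higher. Those lower were the cartilage matrix genes ucmaa (-0.76, adjusted p = 0.0104) and ucmab (-0.67, adjusted p = 0.0183) and the collagen gene col11a1a (-0.48, adjusted p = 0.0292). The cartilage call (adjusted p = 0.0244, and adjusted p = 0.438 with an estimated correlation) was lost without wild type replicate 2 (adjusted p = 0.0618), 1 member was lower without wild type replicate 1, and 1 was higher without mutant replicate 2. The ucmab call was lost without mutant replicate 3 or wild type replicate 1 (0.0501 to 0.0502), and that of col11a1a without mutant replicates 1, 2 or 4 or wild type replicates 1, 3 or 4 (0.0624 to 0.0816).

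Of 82 ribosomal protein genes, 35 were lower, 2 higher and 45 did not pass (71 lower and 4 higher when adjusted over the list alone). Those lower included rps24 (log2 fold change -0.60, 536 ± 57.6 against 811 ± 121 CPM, adjusted p = 0.0140) and rps2 (-0.57, 1933 ± 174 against 2870 ± 399 CPM, adjusted p = 0.0156). Those higher were rpl22l1 (1.87-fold, 290.5 ± 31.9 against 156 ± 29.0 CPM, adjusted p = 0.00244) and rpl3 (1.51-fold, 4489 ± 309 against 2981 ± 415 CPM, adjusted p = 0.0125). The list was called lower (adjusted p = 1.77e-13), but not with an estimated correlation (adjusted p = 0.509). Members lower numbered 2, 6, 2 and 55 without mutant replicates 1 to 4 and 8 and 17 without wild type replicates 1 and 4, and 4 were higher without wild type replicate 2. The gene rpl10a (ENSDARG00000042905), named in the title of the series, had 1352 ± 144 against 1036 ± 155 CPM (1.3-fold) and did not pass (adjusted p = 0.0784), but did so without wild type replicate 2 (log2 fold change 0.49, adjusted p = 0.0171).

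**Figure D2:**
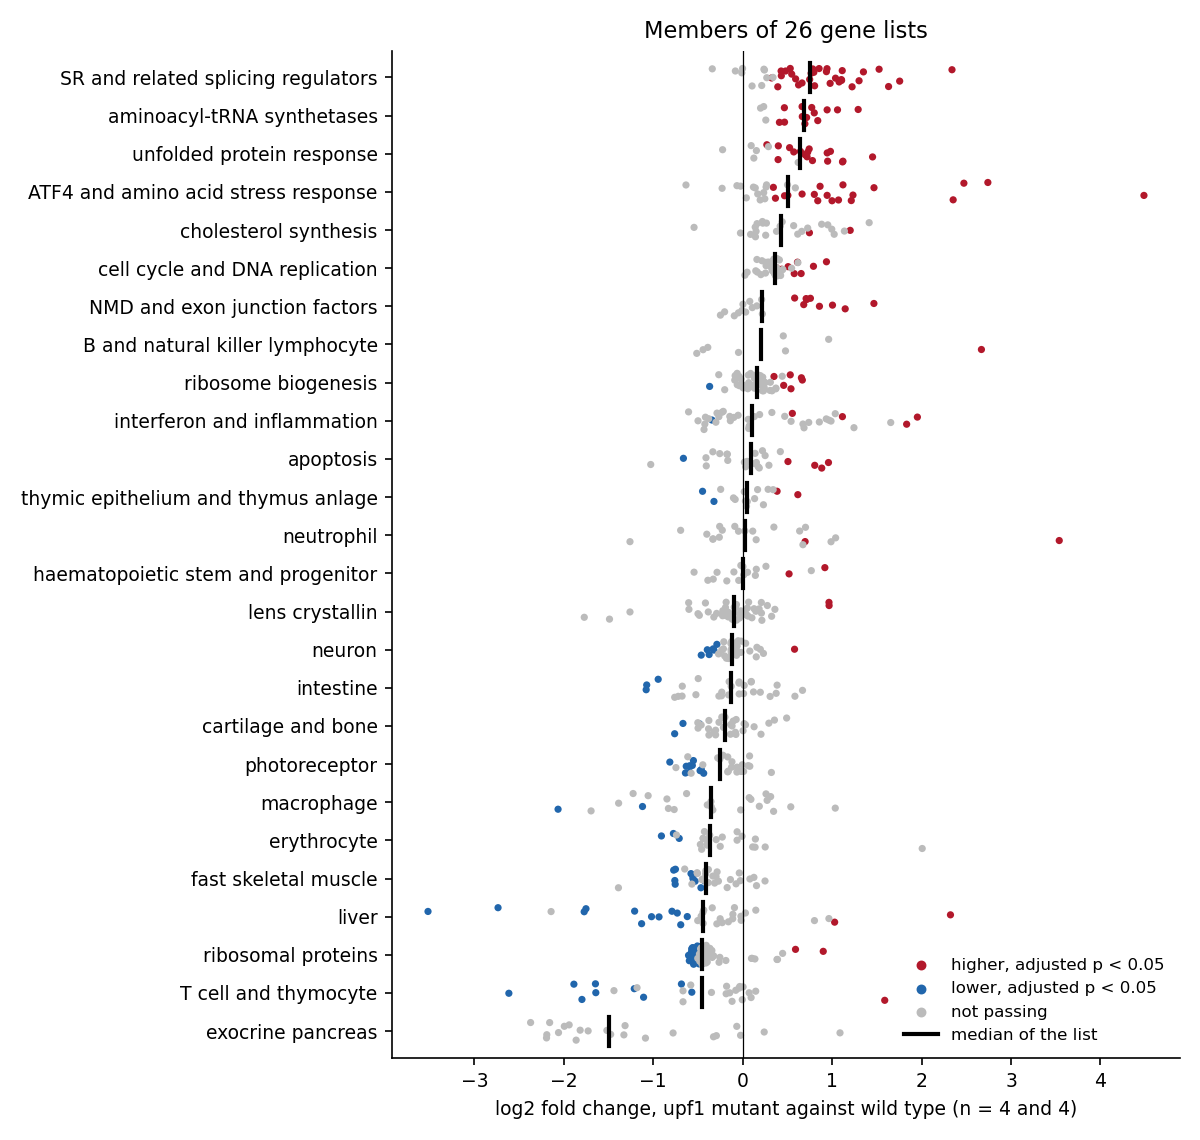
Log2 fold change of each member of 26 gene lists, upf1 mutant against wild type (n = 4 and 4); red and blue points passed the test over all genes, grey points did not, and the black bar is the list's median. Medians run from -1.5 for exocrine pancreas genes to 0.75 for SR and related splicing regulators.

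Ribosome biogenesis genes had 6 of 50 members higher, 1 lower and 43 not passing (5 higher and 1 lower when adjusted over the list alone). They included the small nucleolar ribonucleoprotein genes nop56 (1.45-fold, 252 ± 3.07 against 174 ± 20.2 CPM, adjusted p = 0.00503) and GAR1 (1.58-fold, adjusted p = 0.0110). The helicase gene ddx21, named after its values were seen, fell (log2 fold change -0.37, adjusted p = 0.0280). Members higher numbered 2 without mutant replicates 1 or 3 or wild type replicates 3 or 4, and 17 without wild type replicate 1, and the ddx21 call was lost without mutant replicates 1, 2 or 3 or wild type replicates 1 or 4 (0.0539 to 0.0771). The list's call (adjusted p = 0.0244, and adjusted p = 0.766 with an estimated correlation) was lost without mutant replicate 2 (0.0562) or wild type replicates 3 (0.131) or 4 (0.161). Of 44 cell cycle and DNA replication genes, 8 rose, 0 fell and 36 did not pass (10 rose and 0 fell when adjusted over the list alone). In edgeR 0 were lower at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 lower. The replication helicase gene mcm7 stood at 133.5 ± 9.155 against 69.7 ± 12.6 CPM (1.91-fold, adjusted p = 0.00103). The members cdc45 (1.57-fold) and orc6 (1.73-fold) passed except without wild type replicate 3 (adjusted p = 0.0573 and 0.0604). The cell cycle list was called higher (adjusted p = 4.63e-06, and adjusted p = 0.509 with an estimated correlation), with 4 members higher without mutant replicates 2 or 3, 3 without wild type replicates 1 or 4, 24 without wild type replicate 2 and 1 without wild type replicate 3. Of 26 cholesterol synthesis genes, stard4, a sterol transport gene, was 2.3-fold higher (21.0 ± 4.21 against 9.14 ± 1.37 CPM, adjusted p = 0.00127) and the mevalonate kinase gene MVK 1.68-fold higher (adjusted p = 0.0359), a call lost without any 1 mutant but replicate 4 or without wild type replicates 1, 3 or 4 (0.0518 to 0.096). In all 2 rose and 0 fell (1 rose and 0 fell when adjusted over the list alone), with 1 lower at an unadjusted p under 0.05 in edgeR, 1 in DESeq2 and 0 in limma voom. There was 1 member higher without mutant replicates 1, 2 or 3 or wild type replicates 3 or 4, and 1 lower without wild type replicate 2. That list was called higher (adjusted p = 0.0265, and adjusted p = 0.715 with an estimated correlation), but not without mutant replicate 3 (0.324) or wild type replicates 2, 3 or 4 (0.0560, 0.0832 and 0.0791).

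**Figure D3:**
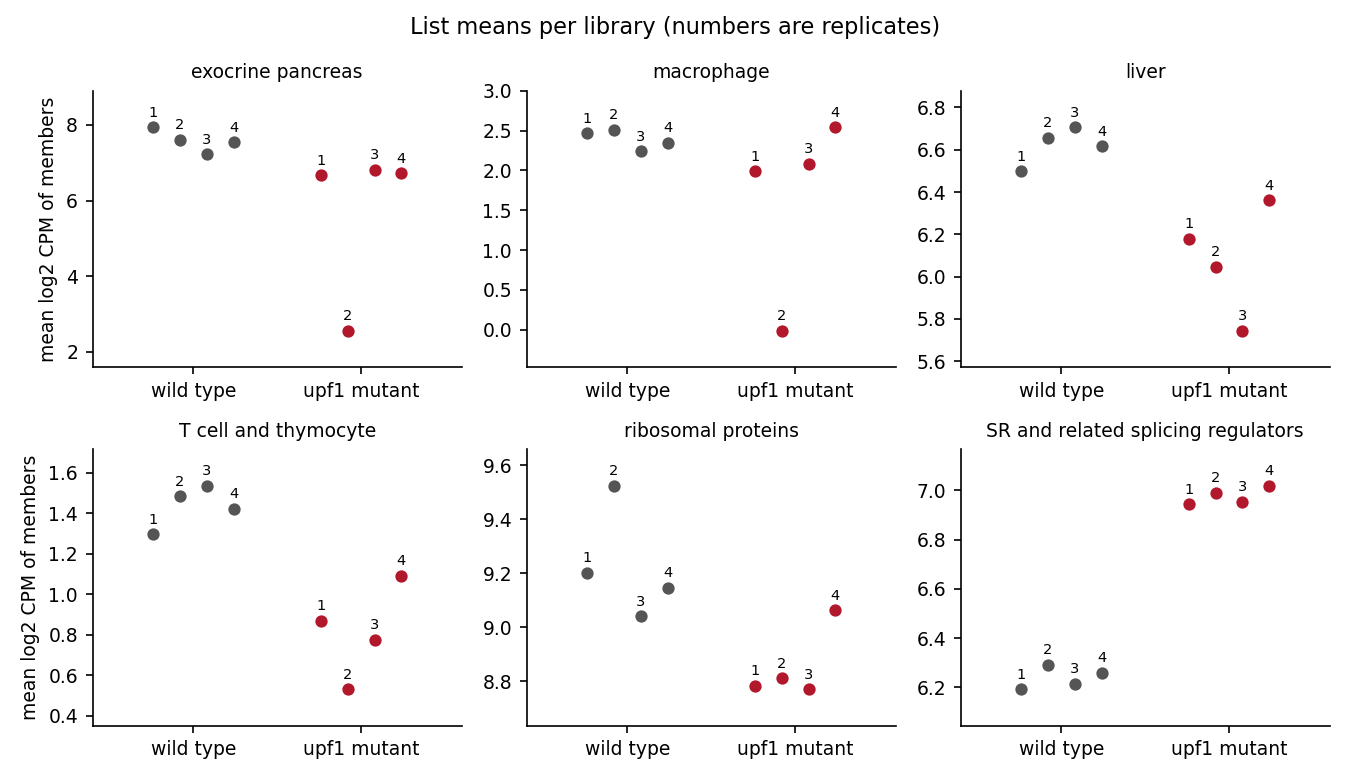
Mean log2 CPM over the members of 6 gene lists in each library (points, with the replicate number above; grey, wild type; red, upf1 mutant); the vertical axes differ and do not start at 0. Mutant replicate 2 stands at 2.56 for exocrine pancreas genes and at -0.01 for macrophage genes, while the splicing regulators of all 4 mutants lie between 6.94 and 7.02 against 6.19 to 6.29 in wild types.

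At the level of single transcripts, the authors' deposited table gave a q-value for 44587 transcripts, and the others had none. Of those with one, 2880 (6.46%) had q under 0.05 in the authors' deposited table. The authors' deposited table lists neither an effect size nor gene names, so direction and identity are not given here. Of the 22293 transcripts above the median abundance in the authors' deposited table, 2094 (9.39%) had q under 0.05.

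Splicing tables of the authors compare 2 sets of 4 values each. The authors' deposited tables do not name the sets, so they are called the first and second set, and no direction by genotype is drawn here. In the authors' deposited tables, 3340 of 37768 events (8.84%) in 2380 genes passed an FDR of 0.05, and 1517 of these in 1141 genes also differed by at least 0.1 in inclusion level. The inclusion level is the listed estimate of the share of the form with the alternative part. It is not the plain share of the junction reads. Skipped exons were the largest class, with 2702 of 30752 events passing in the authors' deposited table, 383 more included and 2319 less included in the first set. Retained introns passed most often, with 102 of 711 events in the authors' deposited table (14.3%; 39 more and 63 less retained in the first set). The authors' deposited tables also had 321 of 4366 mutually exclusive exon pairs (163 and 158 in each direction), 85 of 668 alternative 5' splice sites (51 and 34) and 130 of 1271 alternative 3' splice sites (67 and 63) passing.

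**Figure D4:**
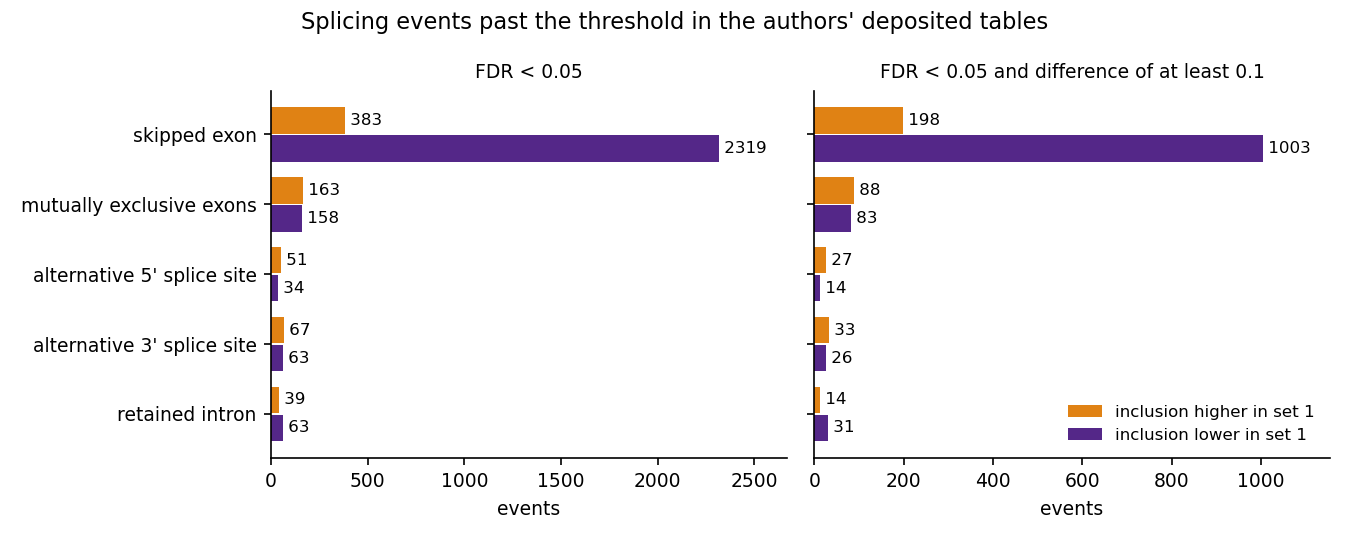
Number of splicing events past the FDR threshold in the authors' deposited tables by class (left), and of those with an inclusion difference of at least 0.1 (right); orange, more included in the first set (set 1), purple, less included. Skipped exons less included in the first set make up 2319 of the 3340 events on the left.

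The ribosomal protein gene rpl10a used an alternative 5' splice site differently in the 2 sets. In the authors' deposited table, the far site adds 301 bp to an exon of rpl10a (chromosome 8, 23718760 to 23719060, plus strand, GRCz10), which ends at 23718759 with the near site. The far site's inclusion level in the authors' deposited table was 0.412 in the first set (range of 4 values 0.395 to 0.428) and 0.0258 in the second (0.023 to 0.028), a difference of 0.387 with a listed FDR of 0. It rested, per the authors' deposited table, on 66893 junction reads for the far site and 47660 for the near site in the first set, and on 3421 and 64461 in the second. For the whole intron at 23718760 to 23719147, the authors' deposited table listed a retention level of 0.302 in the first set against 0.0395 in the second (FDR 0). The first 301 bp of this intron are the part that the far site adds, so reads of the far-site form may count as retention. This level is thus not separate from the far-site difference. For the 87 bp between the far site and the next exon (23719061 to 23719147), the authors' deposited table listed 0.0755 against 0.739 (FDR 0). The spliced form of this event uses the far site, which was little used in the second set. The higher level there is thus not separate from the far-site difference either, and need not mean more retention. The authors' deposited table also listed 2 mutually exclusive exon events over the same exons, with differences of -0.249 (FDR 0) and 0.137 (FDR 2.14e-13), and the alternative 3' splice site and 3 skipped exon events of rpl10a had an FDR of 1.

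**Figure D5:**
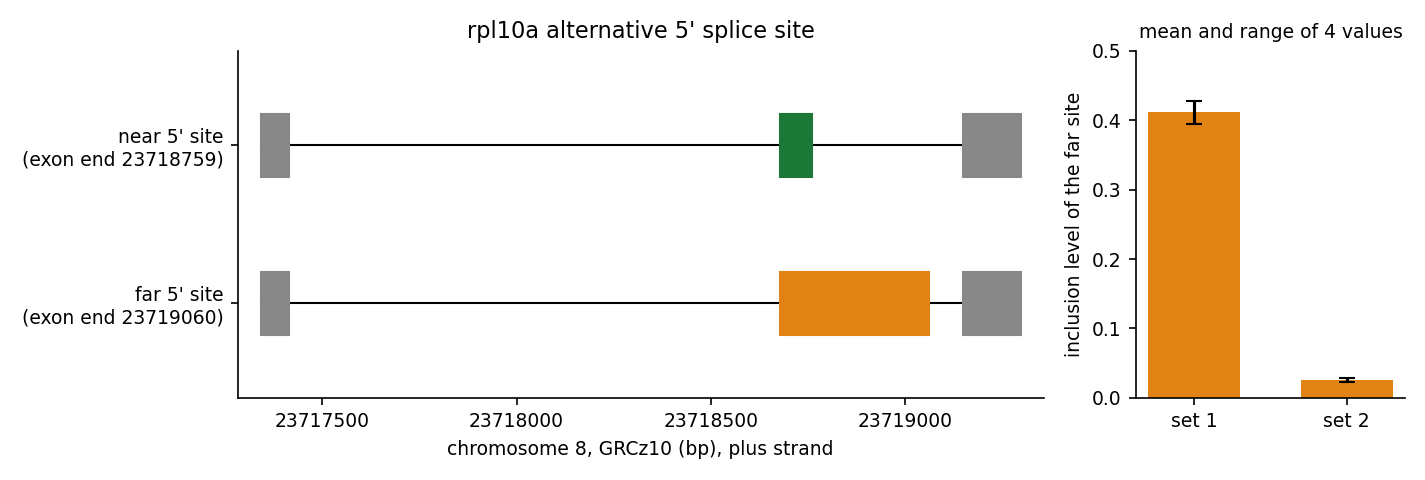
Exons around the alternative 5' splice site of rpl10a on chromosome 8 (GRCz10, position in bp), with the near site (green) and the far site (orange), and at right the far site's inclusion level in the authors' deposited table (bars, mean of 4 values; lines, their range). The level is 0.412 in the first set (set 1) and 0.0258 in the second (set 2).

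Other ribosomal protein genes had passing events too, and in the authors' deposited table, a 68 bp extension at an alternative 3' splice site of rpl22l1 (chromosome 24, 26332484 to 26332551) had an inclusion level of 0.631 in the first set and 0.0295 in the second. For rpl3, the authors' deposited table listed a 231 bp extension at an alternative 3' splice site (chromosome 3, 29738358 to 29738588) at 0.448 against 0.0283, and for rplp1 an alternative 5' splice site with a difference of 0.03 (FDR 0 for all 3). Exons of splicing regulator genes also differed, and in the authors' deposited table, an exon of srsf2a (chromosome 12, 31607295 to 31607401) was included at 0.75 against 0.0085, an exon of hnrpdl (chromosome 10, 5017934 to 5018037) at 0.727 against 0.047, and an exon of hnrnph1 (chromosome 14, 6688771 to 6688909) at 0.218 against 0.885 (FDR 0 for all 3). Among NMD factors, the authors' deposited table listed exons of xrn1 (difference -0.07, FDR 4.22e-07) and nbas (-0.263, FDR 4.94e-07).

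Outside those lists, the largest differences among the smallest FDR values per class in the authors' deposited table were exons of CELA1 (ENSDARG00000095462, chromosome 22, 7443103 to 7443203, 0.0968 against 1) and ITIH4 (chromosome 11, 36951058 to 36951075, 0.0983 against 1), and mutually exclusive exons of bfb (0.153 against 0.982) and cyp4v8 (0.719 against 0.013). The CELA1 event rested on 234 including and 1050 skipping junction reads in the first set and 853 and 0 in the second in the authors' deposited table, and its assignment is uncertain because elastase genes are near-identical. For alternative splice sites, the authors' deposited table gave kdm1a (5' site, chromosome 17, 28082351 to 28082359, 0.439 against 1), fam206a (5' site, 0.364 against 0.865) and fam133b (3' site, 0.4 against 0.918), and for retained introns C2H6orf52 (0.294 against 0.832).

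Genes of the splicing regulator list carried passing events more often than other genes. Of 36 such genes with an event in the authors' deposited table, 26 (72.2%) had one that passed, against 18.9% of other genes (Fisher's exact test, two-sided, adjusted p = 1.51e-10 over 27 lists). Liver genes did so too, with 12 of 27 in the authors' deposited table (44.4% against 19%, Fisher's exact test, adjusted p = 0.0297). The test over lists took no account of junction depth, expression or the number of events per gene. Genes with more reads or events can pass more often, so these excesses may partly reflect that. The ribosomal proteins (8 of 64, adjusted p = 0.817), the NMD factors (2 of 16, adjusted p = 1) and the T cell genes (1 of 11, adjusted p = 1) did not pass the same exact test on the authors' deposited table.

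Genes with changed splicing were also more often changed in level. Of 2378 genes with a passing event in the authors' deposited table, 661 (27.8%) were called by edgeR, against 15.2% of the other genes among 12410 in both (odds ratio 2.15, Fisher's exact test, two-sided, p = 8.34e-44). Within quartiles of expression the odds ratio was 2.08 (95% interval 1.87 to 2.31) on the authors' deposited table.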

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

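The tests of chance splits and of depth were chosen after the values were seen, and those of label and digestive organs before. A library is listed here where its gap to the nearest of its group, divided by the group's range, was unusually large for 4 values. This held for 22 of 352 groups tested, against 17.6 expected by chance (1 in 20), with 8 in wild type replicate 2.

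Among mutants, replicate 2 stood apart for cpa4 (ratio 0.881, 4.61 CPM against 99.3 to 112 in the others), rhag (0.896, 87.7 against 131 to 136) and cnga3a (0.984, 28 against 21.1 to 21.2). Replicate 4 did so for rbp2a (0.882), mdm2 (0.87) and irf9 (0.85). Among wild types, replicate 2 stood apart for myh7ba (0.841), apaf1 (0.926), tmod4 (0.849), gfi1aa (0.848), crygmx (0.919), gad1a (0.933), ccng1 (0.846) and gnat2 (0.898). Replicate 1 did so for mvda (0.864) and DNAH10 (0.86), replicate 3 for psmd11a (0.844), and replicate 4 for smg5 (0.979) and grna (0.854). Of list means, ribosomal proteins stood apart in mutant replicate 4 (0.863, 9.06 against 8.77 to 8.81 log2 CPM) and lens crystallins in wild type replicate 3 (0.847, 4.92 against 5.28 to 5.35).

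The exocrine pancreas mean was 2.56 log2 CPM in mutant replicate 2, against 6.68 to 6.82 in the other mutants (ratio 0.966). A smaller share of all digestive organs would lower liver and intestine genes, whose medians differed by -0.00141 (quartiles -0.138 to 0.26) and -0.048 (-0.275 to 0.174) from the other mutants, against -4.51 (-4.92 to -4.37) for pancreas and -1.87 for macrophage genes. Depth or scaling, as one factor for the library, would move the lists alike, but the pancreas median lay 4.51 below the liver median. A wild type library under a mutant label was also tested: 81.1% of genes called without the library lay nearer the mutants, below the 90% set beforehand, but the other mutants reached 83.2% to 91.9% and wild types at most 27.8%, a comparison chosen afterwards. Less pancreas tissue in the larvae of that library, or its loss before sequencing, may explain the values, and neither was tested.

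Of the 35 splits of the 8 libraries into groups of 4, 1 gave as many changed genes as the real one, which was the real split itself. It gave 3382 genes and the highest other gave 3. Every other split mixed mutants with wild types, so a genotype difference would widen the spread within its groups and lower its count. The real split could rank no better than 1 of 35, so this test cannot exclude chance. Nor can it tell genotype from a difference of clutch or batch.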

How the results depend on the processing

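All alternatives here were planned before the data were examined. Of 129 named genes called, 119 were tested under every alternative and 88 were called under each, and 0 reversed where tested. The other 10 (THEMIS, ZAP70, ccr9b, cd4, cd4-2.2, il7r, lck, cd79a, illr4 and ifit14) were too low to be tested with a CPM of 1 required in 4 libraries. Leaving out 1 library lost between 10 and 25. Without 1 library, genes higher ranged from 1435 to 2267 and genes lower from 675 to 1279, against 2159 and 1223 with all libraries. The DESeq2 Wald test called 2107 genes lower and 367 lower by over 2-fold. In edgeR 241 were lower by over 2-fold, and 157 with a CPM of 1 required in 4 libraries, where 19993 genes were tested against 23680. The cause of the DESeq2 counts was not tested. Of 20 lists called by camera, 4 were called with an estimated correlation and 14 whichever library was left out. Fry called 11 lists, 10 of them among the 20 and the other the apoptosis list. Fry tests whether the members changed at all, while camera compares them with other genes, so a fry call does not repeat a camera call. Some lists not called by camera with an estimated correlation were called by fry. They were the T cell (fry adjusted p = 0.00205), synthetase (0.00156), unfolded protein (3.32e-04), liver (0.014), fast skeletal muscle (0.0367) and cartilage (0.0298) lists. The cause was not tested. Transcripts numbered 1173 at q under 0.01. Events with an inclusion difference of at least 0.2 numbered 594, of which 470 were skipped exons, 55 mutually exclusive exons, 17 alternative 5' sites, 30 alternative 3' sites and 22 retained introns, since the threshold is stricter. Transcript effect sizes are not in the table, so alternatives that need them and the biotype split were not run. In the simulated counts the test found 22.4% of 1.5-fold changes. Few genes were changed there, with 128 calls against 3382 in the data, so the adjusted threshold was harder to pass. Small changes can be missed in the data too, but the share missed is not known.

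Same-number correlations gave no sign that the replicate numbers pair the samples, at 0.023, 0.034, -0.067 and -0.051. Not every sample correlated best with its own number, but with so few libraries a pairing cannot be excluded. With the replicate number as a block, 1379 genes were higher and 666 lower, and 31 of the 129 named genes lost their call. Members lower went from 35 to 2 for ribosomal proteins, 11 to 3 for fast skeletal muscle and 9 to 3 for T cells, and 0 list calls by camera changed.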

Other observations

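The gene families and the tests of set order, reading frame and chromosome were chosen only after the results were seen, and the test of junction depth before. Of 268 families of genes with a shared symbol start, 26 were called by camera and 0 with an estimated correlation (smallest adjusted p = 0.0886). Of 17 dhx helicase genes, 9 rose, such as dhx9 (2.24-fold, 137 ± 7.51 against 61.2 ± 1.26 CPM) and dhx36 (1.95-fold). Of 12 prpf splicing factor genes, 4 rose, such as prpf38b (3.63-fold) and prpf39 (2.51-fold), and 11 of 17 psmd proteasome genes rose, such as psmd3 (1.41-fold) and psmd11a (1.33-fold). Of 12 dnah dynein genes, 7 rose, such as DNAH10 (2.01-fold) and dnah1 (1.52-fold), and 8 of 27 ugt detoxification genes fell, such as ugt5b4 (-1.55) and ugt5d1 (-1.37).

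The sets of the splicing tables are not named, but junction reads argue against the first set holding the wild types rather than the upf1 mutants. Across 11924 genes, the ratio of junction reads, first to second set, correlated with the fold change of the counts, mutant to wild type. Spearman rho was 0.907, genes not being independent replicates, and 200 shuffles of the genes reached at most 0.0248. Of 2136 called genes, 2124 lay on the same side, and upf1 itself had 19811 against 8037 junction reads.

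Most passing skipped exons were less included in the first set. The counts that follow cover exons with a mean of at least 10 junction reads per library. Low junction depth is argued against, since 80.7% of passing exons in the deepest quartile were less included. A candidate explanation is that transcripts with a broken reading frame are kept in that set: 72.8% of 2286 less included exons had a length that is not a multiple of 3, against 15889 of 26863 not passing (odds ratio 1.87 within depth quartiles, 1.7 to 2.06). Such lengths were less frequent among the 374 more included exons (41.2%, odds ratio 0.479, 0.389 to 0.589) than among those not passing.

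Positions came from the splicing tables, so only tested genes with a splicing event were placed on chromosomes. On chromosome 2, which holds upf1, 133 of 580 such genes changed (22.9% against 17.3% elsewhere), with an adjusted p of 0.00989 over 25 chromosomes by Fisher's exact test. Chromosome 4 had the same adjusted p with a lower share (61 of 511 genes, 11.9% against 17.8% elsewhere), so chromosome 2 was not alone in standing apart. A haplotype carried with the mutation could give this, but genes within 10 Mb of upf1 changed about as often as the rest of the chromosome (odds ratio 1.03, 0.572 to 1.78), an interval too wide to decide.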
